A study of Mus musculus with 13 samples.

How the data were processed

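The series measured, by chromatin immunoprecipitation followed by sequencing (ChIP-seq), where 3 proteins sit on the genome of NU1 cells, a mouse urothelial cell line that became immortal spontaneously. The antibodies were against STAG1, STAG2 and CTCF. Each was used on proliferating and on quiescent cells with 2 biological replicates, which gives 6 groups and 12 libraries. Per the labels, each precipitation used 25 ug of antibody and 550 ug of chromatin. Cells were made quiescent by growth to confluence followed by medium with 1 uM rosiglitazone, which activates the nuclear receptor PPAR gamma, and 0.5 uM erlotinib, which inhibits the EGF receptor kinase. A further sample, titled input but labelled with an IgG antibody, was not analysed here, so whether the fold enrichments were measured over input chromatin or over an IgG precipitation was not settled.

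Per the submitters' processing notes, the tools named were bcl2fastq, BWA, Picard, MACS2 and HOMER, with the mouse build mm10; their versions were not given in the sources used here. The authors deposited one list of peaks per library, so replicates were not pooled and their lists could be compared. Each deposited list gives for every peak a fold enrichment over background, a -log10 p-value and a -log10 q-value as the authors' peak caller wrote them, and the summit's offset from the start. Those fold and q-values are the authors'. They were used only to describe, rank or filter peaks within a list. The smallest peak was 330 bp wide in every library, the same number as the 450 bp mean fragment size of the labels less 120 bp of adaptors. The smallest -log10 q in a library lay between 1.31 and 1.57.

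The deposited lists hold no read totals. The fold enrichments below 12 fell on whole multiples of a common step in each library, within a tolerance of 0.0005, for between 31.8% and 48.1% of those peaks. The step lay between 0.4989 and 0.49909 over the 12 libraries. If fold enrichment is the pileup plus 1 over the background plus 1, as the caller usually computes it, the step gives a background of 1.00 reads per position in every library, with a spread of 0.076%. Only a narrow range of steps was searched, so a background of about 1.00 was set by the search, while its small spread was not. With such a background the libraries may have entered peak calling at nearly equal depth, but this was not shown. The deposited peak names mark each library and its input as normalised without saying how. The number of peaks still depends on how well each precipitation worked.

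Libraries were grouped by antibody and state from the labels. Peaks were taken to match where they shared at least 1 bp. A site is a set of matching peaks over several libraries. A lost site was called in both proliferating libraries of an antibody and in no quiescent one, and a gained site the reverse. A STAG peak with CTCF matched a peak in both CTCF libraries of the same condition, and one without CTCF matched neither. Peaks on the sex chromosomes and the mitochondrial genome were kept.

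Genes came from a table of the mouse assembly GRCm38.p6, the same build as mm10, with 21883 protein-coding genes. It gives no strand, so the planned promoter windows were replaced by windows of 1 kb on each side of both ends of a gene, one of which holds its start. These are called gene ends. A gene was occupied in a group when a peak of both libraries overlapped one of its gene ends. Genes of a cluster that share an end share its peaks. The design had assumed strands and a genome sequence. A window at the 5' end alone and a search for the CTCF motif were not run.

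The 17 gene lists were written before the data were examined: G2/M and G1/S genes bound by the DREAM repressor complex, DREAM and MuvB subunits, cohesin with its regulators and CTCF, urothelial differentiation, basal urothelium, PPAR gamma targets of lipid metabolism, EGF receptor and MAPK response, CDK inhibitors and growth arrest, Hox genes, clustered protocadherins, ribosomal proteins, replication-dependent histones, olfactory receptors, and markers of fibroblasts, immune cells and neurons. Every written symbol was found in the gene table.

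The numbers of peaks were compared as the mean log2 ratio by an exact two-sided permutation of the state within each antibody, with 216 arrangements. Agreement was the Jaccard index, the shared over the combined length of 2 lists, and the mean within conditions less the mean between them was tested by an exact one-sided permutation with 27 arrangements. Shares of peaks with CTCF were compared by exact two-sided permutations of 36 arrangements. Shares within a library were compared by exact sign flips, 256 over the 8 STAG libraries and 16 over the 4 quiescent ones. Counts of lost, gained and protein-specific sites have no p-value and stand beside the same counts for the other ways to split the 4 libraries into pairs. Gene lists were compared with all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 102 tests of occupancy and over another 102 of change. Changes compared lost or gained genes with kept ones. The adjusted threshold was 0.05. P-values of the permutation and sign-flip tests over libraries measure the spread between these libraries. Those of Fisher's test do not, since its units are genes. It asks whether a list stands apart from other genes in these libraries. It also takes genes as independent, which neighbours in a cluster are not.

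The genes named were set by a rule fixed at the same time as the lists. It left out predicted genes named Gm or Rik. It took, for each antibody and direction, the 5 lost or gained sites at gene ends with the highest fold percentile in the weaker of both libraries. It took up to 4 members of each list, those occupied in the most libraries with the highest fold percentile. It also took the 10 strongest STAG2 sites at gene ends in all 4 STAG2 libraries and no CTCF library, the 5 strongest of these without STAG1, and the 10 sites with the highest mean percentile over all 12 libraries, named by the gene they lie in or the nearest gene. Genes named outside this rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

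Alternatives were a -log10 q of at least 5, the 20000 peaks with the highest -log10 q in each library, CTCF included, summits at most 200 bp apart, a reciprocal overlap of 0.5, windows of 2 kb, another gene background, occupancy in either library, a replicate block, comparison within 5 ranks of fold enrichment, and leaving out each library in turn. The scripts were tested on simulated data: of 30600 simulated sites in 4 libraries, all 1500 planted losses and all 600 planted gains were found. Each simulated site was called in every library where it was planted. The test therefore checked the code and not how reliable lost and gained calls are in the real lists. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.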

Results

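STAG1 and STAG2 are alternative subunits of cohesin, the ring complex that holds DNA loops and sister chromatids, and CTCF is the zinc finger protein at which cohesin often stops. Their binding was mapped in proliferating and quiescent NU1 mouse urothelial cells, with 2 biological replicates for each of 6 groups. The series addresses how STAG2, a tumour suppressor of the bladder, acts with the DREAM complex, which represses cell cycle genes in quiescence. Lists held between 34281 and 71757 peaks, with median widths from 526 to 564 bp. Between 60.8% and 68.1% of the peaks of a library overlapped a protein-coding gene.

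The site with the highest mean fold percentile over all 12 libraries, 99.95, was at an end of Ivd, which encodes isovaleryl-CoA dehydrogenase, on chromosome 2 from 118883029 to 118884009 in mm10. Its fold enrichment ranged from 62.1 to 110. Other sites of this kind lay at ends of Kiss1r, the kisspeptin receptor, of Scnn1g, a subunit of the epithelial sodium channel, and of Cdkn2aipnl. Sites within Coq7 and Itgb7, and sites nearest to Mab21l3, Rhbdd2, Mecom and Nxph3, completed the 10 highest. Of 114651 sites called in any library, 18250 were called in all 12.

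Both quiescent libraries of STAG1 and of STAG2 held fewer peaks than both proliferating ones, and for CTCF 1 quiescent library held fewer and 1 more. STAG2 had 47295 and 45582 peaks in proliferating cells and 38407 and 34281 in quiescent cells, a mean log2 change of -0.36. STAG1 had 38857 and 50468 peaks in proliferating cells and 35594 and 36680 in quiescent cells, a mean log2 change of -0.29. CTCF had 57528 and 55168 peaks in proliferating cells and 51835 and 71757 in quiescent cells, a mean log2 change of 0.11. Over the 3 antibodies the mean log2 change was -0.18, which did not pass the test (exact permutation p = 0.148, two-sided, 216 arrangements). Without CTCF quiescent replicate 2 it was -0.26 with an exact permutation p = 0.00926. The change of the STAG lists less that of CTCF was -0.44 on the log2 scale (exact permutation p = 0.0833).

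**Figure D1:**
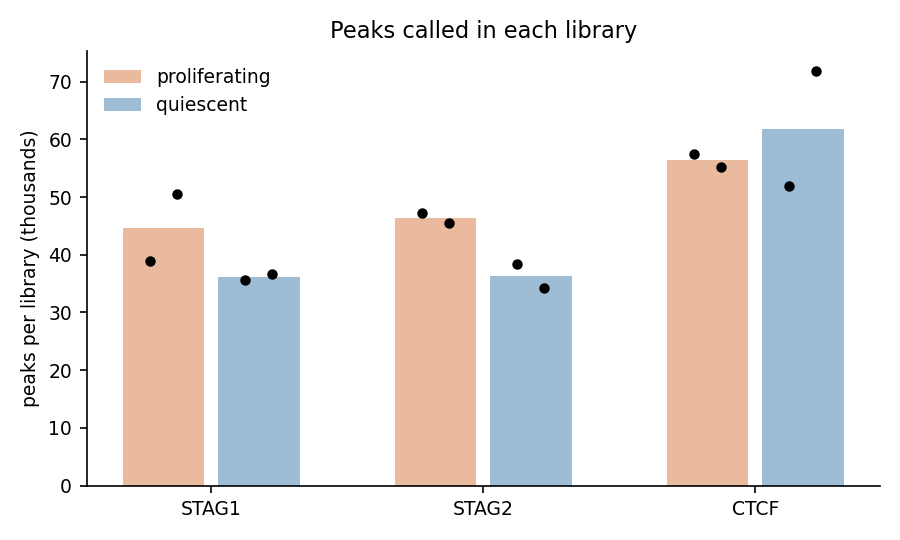
Peaks called in each library (vertical axis, in units of 1000 peaks), by antibody and state. Bars are the mean of 2 libraries, points are single libraries, and the bars start at 0. Both quiescent libraries of STAG1 and of STAG2 lie below both proliferating ones, while the quiescent CTCF libraries, with 51835 and 71757 peaks, lie on either side of the proliferating ones.

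More STAG sites were lost than gained in quiescent cells. STAG2 lost 3567 sites, 10.3% of those called in both proliferating libraries, and gained 579. STAG1 lost 2507 sites and gained 365. CTCF lost 2057 and gained 3479. Sites called in all 4 libraries of an antibody numbered 27091 for STAG2, 25582 for STAG1 and 36411 for CTCF. When the 4 STAG2 libraries were paired across the conditions in place of within them, the highest count of sites held by exactly one pair was 1456, and for STAG1 it was 1778. The lost STAG sites lay above these counts and the gained ones below them. For CTCF that count was 3896, above both its lost and its gained sites. With 20000 peaks in every library STAG2 lost 894 and gained 892 sites, and STAG1 lost 421 and gained 479, so the excess of losses did not hold at equal list lengths.

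The lost STAG2 sites with the highest ranks at gene ends included one at Gmnn, which encodes the replication licensing inhibitor geminin. It lay on chromosome 13 from 24750743 to 24751801 with a mean fold enrichment of 10.9. The others lay at Mns1, Zbtb8os, Pts and Tmem161a. Gained STAG2 sites of this kind lay at C2cd4b, Nell1, Mmp16, Lin7a and Daam2, and the one at C2cd4b, on chromosome 9 from 67759336 to 67760908, had a mean fold of 17.0. Lost STAG1 sites lay at Plekhd1, Arf3, Porcn, Pla1a and Cstad. Gained STAG1 sites lay at Gpnmb, Suv39h2, a histone H3K9 methyltransferase gene, Dmkn, Lrp2bp and Rln3. For CTCF, Lsm5, Nf1, Uchl1, Gpr158 and Cers1 lost a site, and Gnrh1, Rbm34, Nupr1, Cyp4f14 and Ly6g6f gained one. Of the lost STAG2 sites 9.17% lay at gene ends, against 40.9% of those in all 4 libraries and 32.3% of the gained ones. Of the lost STAG2 sites 52.3% and of the gained ones 43.7% matched no CTCF library, against 8.46% of the sites in all 4, so the lack of CTCF was no trait of lost sites alone. For STAG1 these shares were 40.0%, 38.1% and 3.80%, and 14.4% of its lost and 15.3% of its gained sites lay at gene ends, against 36.6% of those in all 4.

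**Figure D2:**
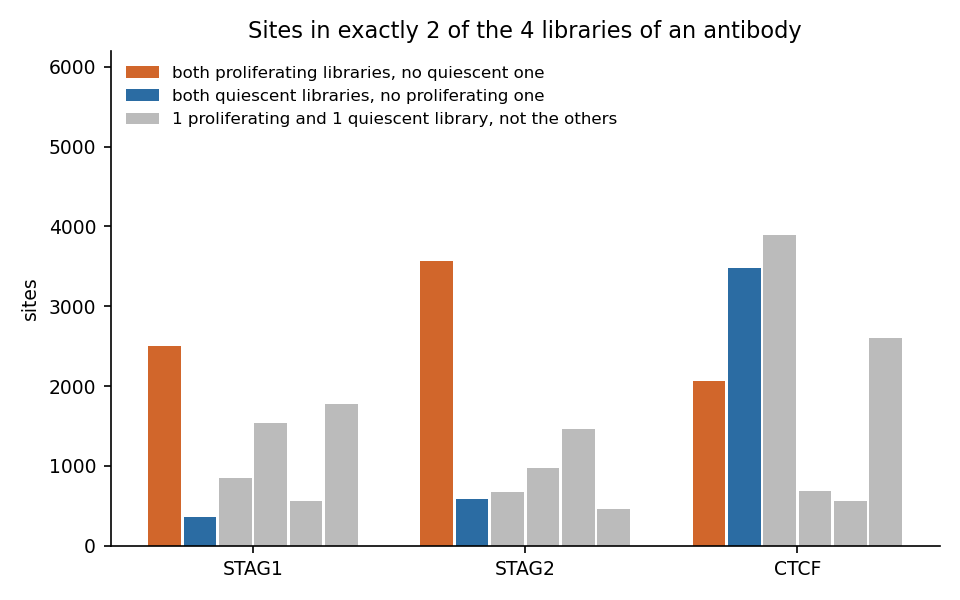
Sites called in exactly 2 of the 4 libraries of an antibody. Orange bars are sites of both proliferating libraries, blue bars those of both quiescent libraries, and grey bars those of 1 proliferating and 1 quiescent library. For STAG2 the 3567 lost sites stand above the highest grey bar, 1456, while for CTCF the highest grey bar, 3896, exceeds both coloured bars.

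Peak sets of one condition overlapped slightly more than sets of different conditions. The Jaccard index of the STAG2 lists was 0.685 between the quiescent replicates, 0.610 between the proliferating ones and 0.605 to 0.612 across conditions. For STAG1 it was 0.641 within quiescence, 0.555 within proliferation and 0.548 to 0.631 across. For CTCF it was 0.567, 0.616 and 0.534 to 0.599. The mean within conditions exceeded the mean between them by 0.0211 (exact permutation p = 0.037, one-sided, the smallest that 27 arrangements can give). With 20000 peaks in every library the difference was 0.0213, about the same size, but no longer passed (exact permutation p = 0.111). The call also ended without either proliferating CTCF library, either quiescent STAG1 library or either quiescent STAG2 library, where the difference lay between 0.00456 and 0.0173 (exact permutation p from 0.0741 to 0.407).

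STAG sites with CTCF were more often called again in quiescent cells than STAG sites without it. Of the STAG2 sites of both proliferating libraries, 91.7% ± 1.82 (SD, n = 2) of those with CTCF and 56.1% ± 2.75 of those without were called again in a quiescent library. For STAG1 these shares were 92.0% ± 0.524 and 52.7% ± 4.35. The difference was 37.4 percentage points on average and had the same sign in all 4 quiescent libraries (exact sign-flip permutation p = 0.125, two-sided, the smallest the design allows, so it could not reach 0.05). Within ranks of fold enrichment it was 17.6 points, with 20000 peaks in every library, CTCF included, 16.2 points, and with 20000 STAG peaks and full CTCF lists, chosen after seeing the data, 35.5 points. That last cut left 287 STAG1 and 848 STAG2 sites without CTCF, against 3756 and 6734 in the full lists.

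Most STAG peaks overlapped CTCF. In quiescent cells 65.6% ± 2.85 (SD, n = 2) of STAG2 peaks and 70.5% ± 1.15 of STAG1 peaks matched both CTCF libraries, and in proliferating cells 60.1% ± 2.07 and 65.3% ± 9.76. The STAG2 share minus the STAG1 share was -5.02 percentage points on average, which did not pass the test (exact permutation p = 0.222, two-sided) and ranged from -8.47 to -1.56 points when 1 library was left out. With one CTCF list for both conditions, the share was 63.4% ± 2.66 in proliferating and 72.8% ± 2.96 in quiescent cells for STAG2, and 69.3% ± 10.6 and 77.6% ± 1.16 for STAG1. The mean difference of 8.80 points had an exact permutation p = 0.0556, the smallest that 36 arrangements can give, so the design could not reach 0.05. It ranged from 5.07 to 12.5 points when 1 library was left out. It was 0.219 points with 20000 peaks in every library, CTCF included, and 1.57 points when the STAG lists alone were cut to 20000, a test chosen after seeing the data.

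Some of the STAG2 sites held in both states had no CTCF. Of 27091 STAG2 sites in all 4 libraries, 2292 matched no CTCF library, and 526 of these lay at a gene end with a named gene. The strongest was at Arrdc4, an arrestin family gene, on chromosome 7 from 68748352 to 68749611, with fold enrichments from 31.5 to 52.6. Others among the strongest were at Daxx, a histone H3.3 chaperone gene whose site is shared with Zbtb22, and at Tmem241, Mcoln1, Hexim1, which encodes an inhibitor of the elongation factor P-TEFb, Pias4, Inpp5j, Tspan31 and Lancl1. The sites at Daxx, Pias4, Inpp5j and Tspan31 matched no STAG1 library either.

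Over all peaks, those without CTCF lay less often at gene ends. Among STAG2 peaks the shares were 14.5% ± 0.723 (SD, n = 2) without and 36.1% ± 2.00 with CTCF in proliferating cells, and 26.6% ± 1.24 and 37.9% ± 0.762 in quiescent cells. Among STAG1 peaks they were 15.7% ± 0.396 and 34.3% ± 1.01, then 24.7% ± 0.743 and 34.4% ± 0.0188. The mean difference over the 8 STAG libraries was -15.3 points, with the same sign in all 8 (exact sign-flip permutation p = 0.00781, the smallest the design allows). The STAG libraries of a state were split by the same CTCF libraries, so the 8 differences were not independent, as the test takes them to be. With 20000 peaks in every library, CTCF included, the direction reversed, and peaks without CTCF lay at gene ends more often by 14.0 points (exact permutation p = 0.0156). Shorter CTCF lists turn peaks with weak CTCF into peaks without it. With the STAG lists alone cut to 20000, a test chosen after seeing the data, the difference was -9.82 points (exact permutation p = 0.0469), with a mean of -18.7 points in the proliferating and -0.963 in the quiescent libraries. Only 719 to 1526 peaks per library were then without CTCF.

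**Figure D3:**
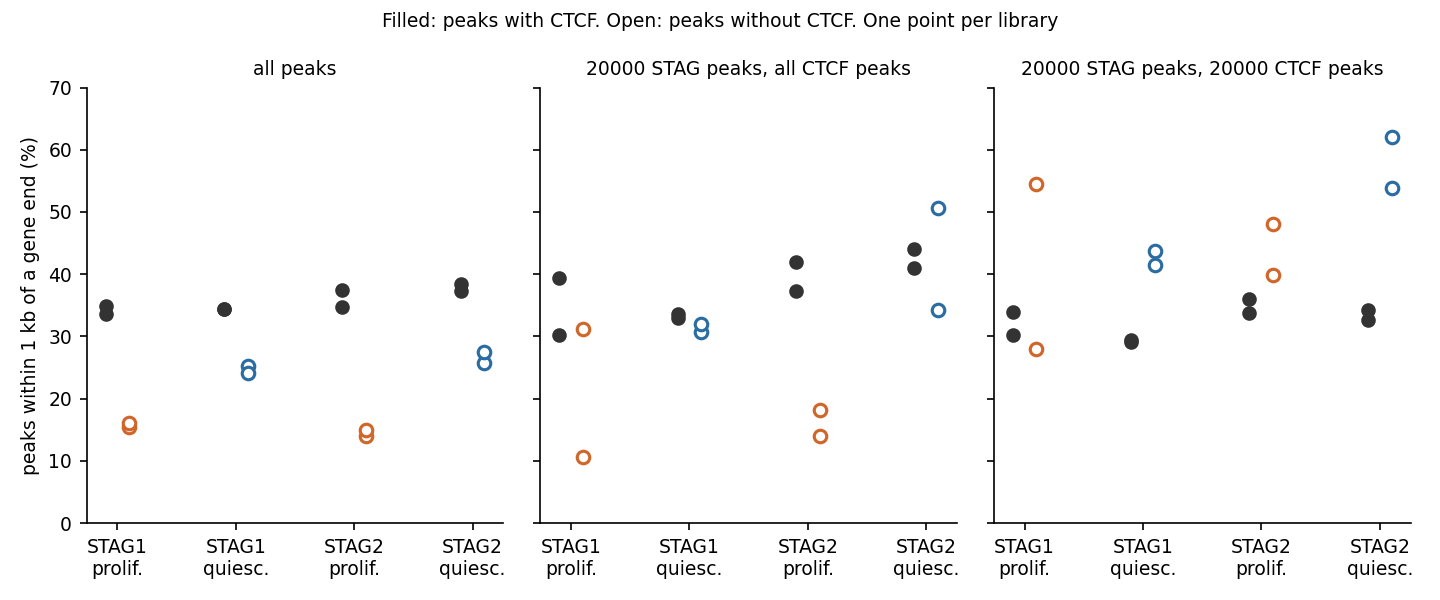
Percent of STAG peaks within 1 kb of a gene end, one point per library, for peaks with CTCF (filled) and without (open, orange proliferating and blue quiescent). The left panel has all peaks, the middle panel 20000 peaks in every STAG library against full CTCF lists, and the right panel 20000 peaks in every library, CTCF included. Open points lie below the filled ones of the same library on the left, below them in the middle except in 1 STAG2 quiescent library, at 50.7%, and above them on the right except in 1 STAG1 proliferating library, at 28.0%.

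Sites called in all 4 STAG libraries of a state numbered 23717 of 51040 in quiescent and 27120 of 69207 in proliferating cells. In quiescent cells 2407 sites had STAG2 in both libraries and STAG1 in neither, and 2092 had STAG1 without STAG2, against at most 941 for the other ways to pair the 4 libraries. In proliferating cells the numbers were 2132 and 1549, no higher than the 2182 found for another pairing.

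Many cell cycle genes listed as DREAM targets had STAG2 at a gene end in both states. DREAM itself was not mapped in these cells, so its binding there rests on the written lists. Of the G1/S list, 52 of 60 genes were occupied by STAG2 in proliferating and 52 of 60 in quiescent cells, 86.7% each, against 54.6% and 54.2% of other genes (Fisher's exact test, odds ratios 5.42 and 5.50, adjusted p = 7.78e-07 and 7.34e-07). In all 4 STAG2 libraries, Chaf1b and Asf1b, which encode histone chaperones, had peaks with fold enrichments of 39.9 to 55.4 and of 39.5 to 52.3, and Tk1, thymidine kinase, and Cdc25a, a CDK-activating phosphatase gene, followed. Chaf1b and Asf1b were not particular to STAG2, since STAG1 and CTCF were called there in all 4 libraries of each. Their mean folds were 54.5 and 52.0 for STAG1 and 60.3 and 64.6 for CTCF. Tk1 had STAG1 in all 4 libraries too. Of the G2/M list, 37 of 49 genes were occupied in proliferating cells, 75.5% (odds ratio 2.56, Fisher's exact test, adjusted p = 0.00889), and 33 of 49 in quiescent cells, 67.3%, which did not pass (adjusted p = 0.132). Kif22, Kif23, Ccna2 and Ccnb1, genes of mitotic kinesins and cyclins, had STAG2 in all 4 libraries. Of the DREAM and MuvB subunits, 12 of 13 were occupied in each state (Fisher's exact test, adjusted p = 0.02 and 0.0115), with E2f5, E2f4, Tfdp2 and Lin9 the highest ranked. Ccna2 and E2f5 also had STAG1 and CTCF in all 4 libraries of each. Kif22 had STAG1, and Kif23 and Tfdp2 had CTCF, in all 4.

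STAG1 occupied 37 of 60 G1/S genes in proliferating and 36 of 60 in quiescent cells, and 32 of 49 and 22 of 49 G2/M genes, against 48.7% and 47.0% of other genes, which were also fewer than for STAG2. The difference between STAG2 and STAG1 was not tested. In proliferating cells it rested on STAG1 replicate 1, which occupied 61.7% of the G1/S and 65.3% of the G2/M list. STAG1 replicate 2 occupied 88.3% and 87.8%, against 86.7% to 90% and 79.6% to 85.7% in the STAG2 libraries. In quiescent cells both STAG1 libraries, with at most 78.3% and 59.2%, lay below both STAG2 libraries, with at least 86.7% and 71.4%. For STAG1, Fisher's exact test passed for the G2/M list (adjusted p = 0.0452) and the DREAM subunits (adjusted p = 0.0235) in proliferating cells and for none of the 3 lists in quiescent cells. CTCF occupied 42 of 60 and 33 of 60 G1/S genes and 24 of 49 and 19 of 49 G2/M genes, and Fisher's exact test passed for the G1/S list in proliferating cells (adjusted p = 0.00674) and for the DREAM subunits in both states (adjusted p = 0.00849 and 0.0202). With 20000 peaks in every library the odds ratios of the G2/M list in proliferating cells were 0.561 for STAG2 and 0.479 for STAG1, and the G1/S list no longer passed Fisher's exact test for STAG2 (adjusted p = 0.596 and 0.111). Against genes with a peak in any library, Fisher's exact test for STAG2 in proliferating cells no longer passed for the G1/S list (adjusted p = 0.0643), the G2/M list (adjusted p = 1) or the DREAM subunits (adjusted p = 0.605), while the G1/S list in quiescent cells did (adjusted p = 0.0496).

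Of the lists of the urothelium, the drugged pathway and growth arrest, 3 were occupied above other genes for STAG2 in both states. For the EGF receptor and MAPK response list, which includes targets of the kinase that erlotinib inhibits, 30 of 31 genes had STAG2 in each state, 96.8%, with Etv5, Dusp1, Dusp5 and Jund highest ranked (Fisher's exact test, adjusted p = 1.7e-06 and 8.22e-07). For the CDK inhibitors and growth arrest list it was 22 of 23 in each state, with Gadd45b, Cdkn2b, Ccng2 and Cdkn2a highest (Fisher's exact test, adjusted p = 8.79e-05 and 8.51e-05). Of the urothelial differentiation list, 26 of 30 and 25 of 30 genes were occupied, with Cdh1, Upk3b, Krt8 and Klf5 highest (Fisher's exact test, adjusted p = 0.00103 and 0.00373). The same 3 lists lay above other genes for STAG1 and for CTCF in both states too (Fisher's exact test, adjusted p of at most 0.00373). The last 2 lists were no longer above other genes for STAG2 when only genes with a peak in any library were the background, with adjusted p of at least 0.209.

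Ribosomal protein genes had STAG2 at 83.1% in each state, with Rps19, Rpl7 and Rpl10a among the highest, and replication-dependent histone genes at 92.2% and 95.3%, with H3c15, H2ac19, H3c14 and H2ac18 highest (Fisher's exact test, adjusted p = 2.86e-07 and 2.7e-07, then 5.71e-10 and 3.72e-12). Histone genes lie close together and share peaks. Both lists lay above other genes for STAG1 and for CTCF too (Fisher's exact test, adjusted p of at most 0.0137). Against genes with a peak in any library the ribosomal list did not pass Fisher's exact test (adjusted p = 0.349 and 0.326), and the histone list passed in quiescent cells alone (adjusted p = 0.00497). The olfactory receptors, silent in most tissues, had STAG2 at 0.814% in proliferating and 0.452% in quiescent cells, 9 and 5 of 1106 (Fisher's exact test, odds ratios 0.00606 and 0.00341), and at most 1.27% for STAG1 and CTCF, and Olfr1373, Olfr1382, Olfr225 and Olfr658 were the highest ranked. Immune cell markers were at 25% in both, below other genes (Fisher's exact test, adjusted p = 0.0452 and 0.0459), and Spi1, Cd14, Cd4 and Cd79a were the occupied ones. That call ended with a -log10 q of at least 5, with 20000 peaks, with 2 kb windows and against genes with a peak (Fisher's exact test, adjusted p of at least 0.0621).

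The 6 lists of this paragraph did not pass the test for STAG2. Basal urothelium genes were at 66.7% and 44.4%, with Itga6, Egfr, Cdh3 and Itgb4 highest ranked, PPAR gamma targets at 57.1% in each state, with Ucp2, Acsl1 and Cpt1a, and Hox genes at 71.8% and 66.7%, with Hoxa9, Hoxb5, Hoxa6 and Hoxa5. Cohesin and CTCF genes were at 73.3% in each state, with Stag2, Pds5a, Pds5b and Smc3, fibroblast markers at 50% in each, with Twist1, Col1a1, Tagln and Zeb1, and neuronal genes at 65% and 60%, with Eno2, Camk2a, Rbfox3 and Tubb3. Over the 17 lists and 6 groups, 40 of 102 tests lay above and 12 below other genes, and 11 lay above when genes with a peak in any library were the background.

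**Figure D4:**
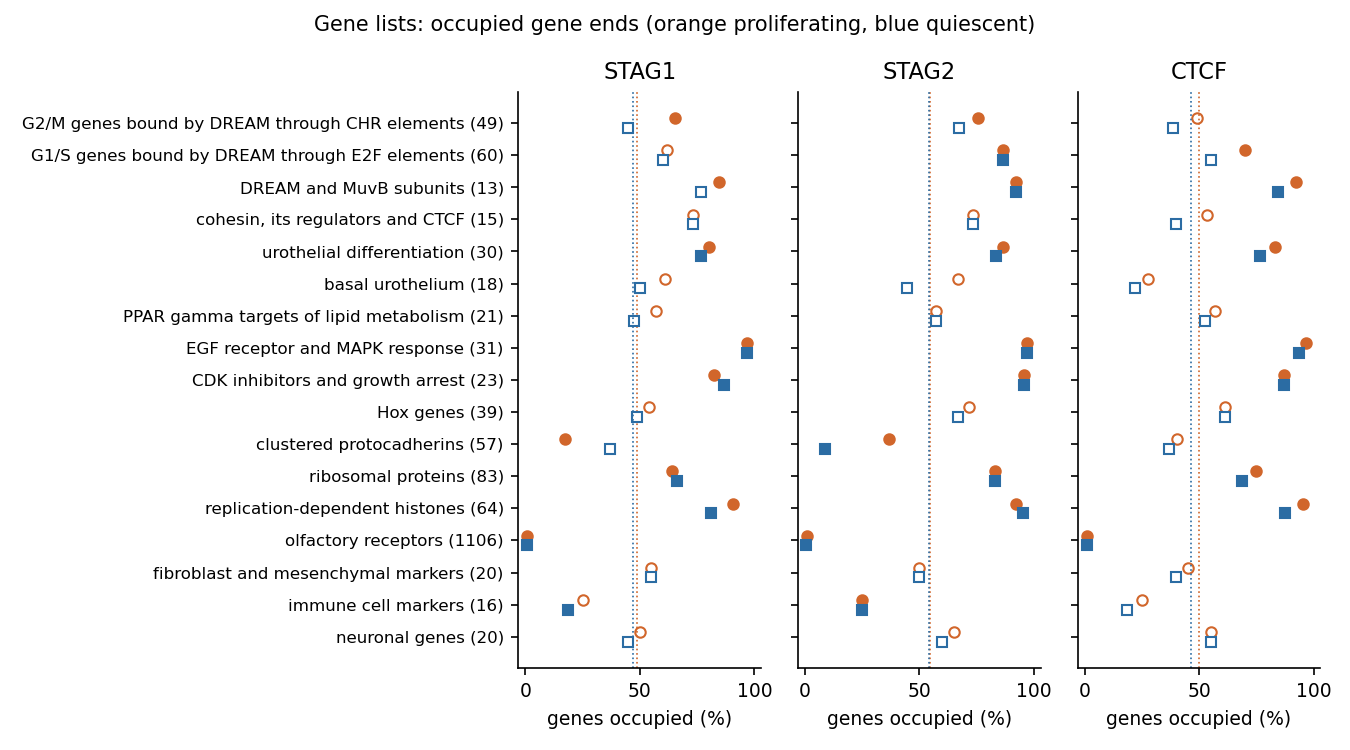
Percent of the genes of each list with a peak of both libraries at a gene end, by antibody. Circles are proliferating and squares quiescent cells, filled where Fisher's exact test passed an adjusted 0.05. List sizes stand in brackets, and dotted lines show the percent of other genes, those outside the bottom list, the neuronal genes. For STAG2 the G1/S list stands at 86.7% in both states and the olfactory receptors below 1%.

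Between the states, 2 of 102 tests of change passed. STAG1 was lost at 5 genes of the G2/M list and kept at 21, against 239 and 9608 other genes (Fisher's exact test, odds ratio 9.57, adjusted p = 0.0194). The 5, named after their values were seen, were Ccnb2, which encodes a cyclin, the kinase gene Plk1, the topoisomerase gene Top2a, the spindle gene Tpx2 and Gas2l3. The STAG1 site at Ccnb2, on chromosome 9 from 70421183 to 70421744, reached a fold enrichment of 10.3, and the sites at the others reached at most 6.28. At Ccnb2 and Gas2l3 STAG2 was called in all 4 libraries. The call of Fisher's exact test ended without STAG1 proliferating replicate 2 (adjusted p = 0.0598), without STAG1 quiescent replicate 1 (adjusted p = 0.2) and with 2 kb windows (adjusted p = 0.189).

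STAG2 was lost at 9 clustered protocadherin genes, adhesion genes arrayed on chromosome 18, and kept at 5 (Fisher's exact test, odds ratio 117, adjusted p = 1.02e-11). The list's STAG2 occupancy, 36.8% in proliferating and 8.77% in quiescent cells, was below that of other genes in both (Fisher's exact test, odds ratios 0.483 and 0.0806, adjusted p = 0.0171 and 5.29e-12). Against genes with a peak in any library the former no longer passed Fisher's exact test (adjusted p = 0.0599). Pcdhgc3, Pcdhgb4, Pcdhgb7 and Pcdhga10 held STAG2 in all 4 libraries. All 9 losses came from 1 site, from 37841172 to 37841710, at the end that the gamma protocadherin genes share. Its STAG2 fold enrichment was at most 5.67, while CTCF was called there in all 4 libraries with folds of 12.0 to 17.0, and STAG1 in 1 proliferating and both quiescent libraries. The number of lost genes therefore counts 1 site 9 times, and with a -log10 q of at least 5 there was 1 lost gene (Fisher's exact test, adjusted p = 0.93).

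**Figure D5:**
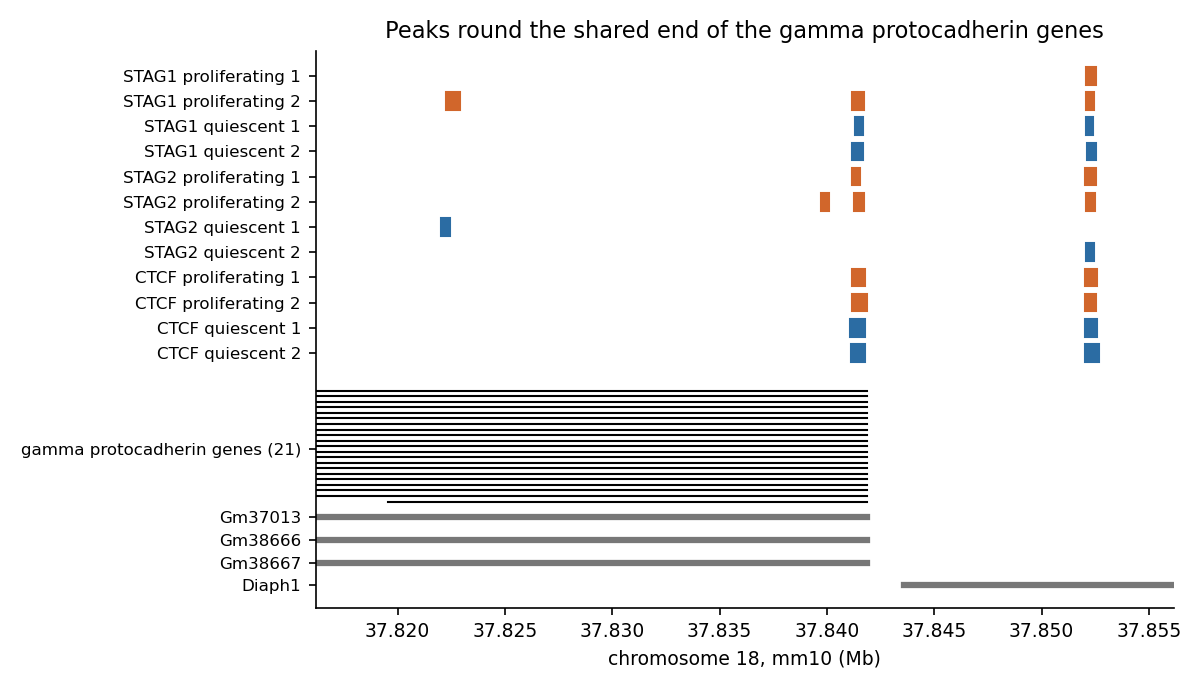
Peaks of the 12 libraries round the shared end of the gamma protocadherin genes on chromosome 18 of mm10, positions in Mb. Boxes are peaks (orange proliferating, blue quiescent), thin lines are the genes as far as they lie in the region, and the genes end together near 37841873. The peak at that end is called by STAG2 in both proliferating libraries and neither quiescent one, and by CTCF in all 4.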

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

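The tests in this part were chosen after the shares at gene ends had been seen.

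The share of peaks at gene ends changed differently for the STAG proteins and for CTCF. In quiescent cells it was 35.7% ± 1.23 (SD, n = 2) for STAG2 and 32.7% ± 0.362 for STAG1, against 29.3% ± 1.31 and 29.1% ± 0.608 in proliferating cells. For CTCF it was 21.0% ± 3.38 against 24.0% ± 1.03. The mean STAG change exceeded that of CTCF by 7.97 percentage points (exact permutation p = 0.0185, two-sided, 216 arrangements). It had the smallest p of 5 measures compared in this way without adjustment, the others being peak number, median fold, median width and the share within genes (exact permutation p of at least 0.0556). It stands here because the change differed between antibodies. Without CTCF quiescent replicate 2, the library with the most peaks, it was 5.58 points (exact permutation p = 0.0278). Without CTCF proliferating replicate 2 it was 7.24 points (exact permutation p = 0.0741), and with 20000 peaks in every library 5.82 points (exact permutation p = 0.213).

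Among STAG peaks without CTCF, the share at gene ends was higher in quiescent cells by 12.1 points for STAG2 and 8.92 for STAG1 (exact permutation p = 0.0556 over both, the smallest the design allows). With 20000 peaks in every library, CTCF included, the difference over both was 7.71 points (exact permutation p = 0.278). The differences of STAG2 alone and of STAG1 alone, with 2 libraries per state, were not tested and are given as values. Shorter lists in quiescent cells, which leave out weak peaks between genes, are argued against as the whole cause for STAG2. There the difference was 14.0 points with 20000 peaks in every library, CTCF included. With 20000 STAG peaks and full CTCF lists it was 26.4 points, over 1312 to 1526 peaks without CTCF per STAG2 library. The quiescent libraries then stood at 50.7% and 34.2% and the proliferating ones at 14.0% and 18.2%. A different CTCF list in each condition is argued against as the whole cause for STAG2, where it was 6.90 points with one CTCF list. For STAG1 these differences were 1.37, 10.4 and 3.15 points, with the proliferating libraries at 28.0% and 54.5% in the first and 10.7% and 31.2% in the second, so neither explanation can be told apart from the state of the cells. Equal STAG lists and one CTCF list were not used together, so both explanations combined stay open for STAG2 too. For STAG2 a redistribution with the state of the cells may be involved, as a hypothesis found and tested on the same libraries, and the quality of the precipitations stays open.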

How the results depend on the processing

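Leaving out the 2 libraries with the most peaks of their antibody together, cutting the STAG lists alone to 20000 peaks, and, for sites called again, ranks of fold enrichment with at least 20 sites and 50 finer ranks, which gave 19.3 and 21.0 points, were chosen after seeing the data; the other alternatives were planned. A window at the 5' end and the motif search were not run for want of strands and sequence, and odds ratios of lists with every member occupied gave no value. Shares of peaks with CTCF, of sites called again and of peaks at gene ends kept their direction under each alternative run, apart from the last with 20000 peaks in every library, given below. List length limits the counts, as read totals are unknown.

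With a -log10 q of at least 5, STAG2 lost 2106 sites. With 20000 peaks in every library, the excess agreement within conditions was 0.0213, losses and gains were 421 STAG1 losses, 894 and 892 for STAG2 and 1041 and 1019 for CTCF, the difference at gene ends reversed to 14.0 points, proliferating cells had 1164 sites of STAG2 without STAG1, and 0 tests of list change passed. Fewer peaks per list account for the smaller counts by construction. CTCF lists were cut there too, which changes which peaks count as without CTCF; with the STAG lists alone cut, the difference at gene ends was -9.82 points on average, but -0.963 in quiescent libraries, 1 of which reversed. With summits at most 200 bp apart STAG1 gained 738 and STAG2 942 sites, and with a reciprocal overlap of 0.5 STAG1 gained 651. With 2 kb windows 1 test of list change passed. Against genes with a peak in any library, 11 list tests lay above other genes. Odds ratios that reversed were those of the G2/M list in proliferating cells with 20000 peaks, 0.479 for STAG1 and 0.561 for STAG2, of that list for STAG1 against genes with a peak, 0.902, and of ribosomal proteins for STAG1 in proliferating cells against the same genes, 0.804. Those of lost against kept G2/M genes for STAG1 and protocadherins for STAG2 with 20000 peaks were 0 because no list gene was lost; the cut drops weak peaks such as most of theirs, so this is no opposite direction.

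Leaving out 1 library at a time, the mean log2 change of peak numbers ranged from -0.26 to -0.10, the excess agreement from 0.00456 to 0.0471, the CTCF share of STAG2 less that of STAG1 from -8.47 to -1.56 points, that of quiescent less proliferating cells from 5.07 to 12.5 points and the number of list changes from 1 to 3. A lone library then defines a group, so counts rose by construction: to 4179 to 15632 losses and 1038 to 2948 gains for STAG1, 5054 to 11997 and 1250 to 3686 for STAG2, and 3186 to 7100 and 5526 to 17834 for CTCF. Sites of STAG2 without STAG1 numbered 3290 to 8678 in proliferating and 3941 to 7390 in quiescent cells, and of STAG1 without STAG2 2274 to 11014 and 2952 to 6108. Without STAG1 proliferating replicate 2 and CTCF quiescent replicate 2 together, the log2 change was -0.19 (exact permutation p = 0.0185), STAG1 lost 6384 and gained 1925 sites, CTCF lost 6285 and gained 6165, and proliferating cells had 6375 sites of STAG2 alone and 4245 of STAG1 alone.

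Replicate numbers are shared between groups, but no label ties equal numbers to one culture or day. Over sites, the deviations of equally numbered libraries correlated at -0.0161 for STAG1, 0.00826 for STAG2 and -0.0374 for CTCF. With a replicate block the change of peak numbers was -0.18, the CTCF share of STAG2 less that of STAG1 was -5.50 points, where CTCF came from the library of the same number alone, and that of quiescent less proliferating cells 8.80 points (exact permutation p = 0.188, 0.125 and 0.125). For both shares 0.125 is the smallest p that 16 arrangements give, so they could not pass 0.05 whatever the data.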

Other observations

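The restriction to ranks of at least 20 sites, the 50 finer ranks and the cut of the STAG lists alone were chosen only after the result was seen. So were the genes of the next paragraph. Tests near genes were written down beforehand only for the basal urothelium, EGF receptor and MAPK response, and urothelial differentiation lists. Those for other lists, and the reverse look-up in full lists, were not. The remaining tests were written down before their results were seen.

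Gata3, which encodes a transcription factor of the urothelium, lost STAG2, and Foxa1 lost CTCF while STAG1 and STAG2 were kept. Of the G2/M and G1/S lists, Kif4, Nuf2, Cdc6 and Nasp lost STAG2 and Cdca8 and Mcm6 gained it, while Anln and Ect2 lost CTCF and Nasp gained it. Of PPAR gamma targets, Pdk4 lost STAG1, Plin5 lost STAG2, Cidec and Lpl lost CTCF, and Plin2 gained CTCF. None of these lists passed Fisher's exact test of lost or gained against kept genes for the antibody named. Over all genes, STAG2 was lost at 183, gained at 132 and kept at 11326. CTCF was lost at 343, gained at 95 and kept at 9691, and STAG1 was lost at 244 and kept at 9629. The lost and gained CTCF sites, 2057 and 3479, were each fewer than the 3896 of a pair across the states. Such CTCF calls at single genes therefore need not reflect the state.

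One hypothesis was that STAG2 sites without CTCF are lost near genes that the drugs or the loss of growth would turn down. Loss was predicted near basal urothelium genes and near EGF receptor and MAPK response genes. Near urothelial differentiation genes the reverse was predicted, that such sites are kept. Of 5523 STAG2 sites of both proliferating libraries that matched no CTCF library of either state, 33.8% were lost. Within 50 kb of basal urothelium genes 13 of 28 sites were lost, at the 90.3 percentile of 10000 random gene sets of the same size. Near EGF receptor and MAPK response genes it was 9 of 42, at the 8.73 percentile, and near urothelial differentiation genes 20 of 58, at the 63.8 percentile. These values lie within the range of random sets, so none of the lists stood apart in the direction named beforehand. G2/M genes had 11 of 34 sites lost, at the 53.2 percentile. Of the 14 lists with at least 5 genes near such a site, Hox genes, with 1 of 7 sites lost, and replication-dependent histones, with 0 of 5, passed adjustment in a permutation test (adjusted p = 0.0308 and 0.0028), but their clustered genes share sites, which random gene sets do not.

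STAG sites without CTCF were called again in quiescent cells less often than those with CTCF. Weaker peaks falling below the threshold could not be excluded as the cause. Within ranks of fold enrichment that held at least 20 sites the difference was 19.3 points. Within 50 finer ranks of the weaker fold of both proliferating libraries it was 21.0 points. The measured fold thus did not account for the whole difference. But the ranks use the fold of the same proliferating lists, so sites of equal rank need not be equally strong. The difference also fell with strength, from 30.4 to 36.2 points in the weakest of 5 ranks to 6.17 to 10.8 in the fourth. In the strongest it was about none for STAG2, where nearly all sites were called again. Weakness may therefore be a part of it or all of it. Shorter quiescent lists are argued against by the values at equal length. With 20000 peaks in every library, CTCF included, the difference was 16.2 points. With 20000 STAG peaks and full CTCF lists it was 35.5 points, over only 287 STAG1 and 848 STAG2 sites without CTCF. Poorer repetition of sites without CTCF between any libraries cannot be told apart from a change tied to quiescence: looked up in the reverse direction, from quiescent to proliferating libraries, the difference was 18.3 points, 113% of the forward one, in the former setting, 20.5 points, 57.9%, in the latter and 13.9 points, 37.2%, in full lists, whose lengths differ. So the answer hung on how the lists were cut, and both stay open.

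The loss of STAG2 at 9 protocadherin genes was a count of genes that share an end, since 1 separate STAG2 site lay behind all 9. Whether STAG2 left that site could not be read from the lists alone, because its fold enrichment was at most 5.67 where it was called. Reads shared between these similar genes were not tested.

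The widest peak of every library lay near the start of chromosome 9, at about the same place, and reached 38.7 kb with fold enrichments between 2.09 and 4.13. Peaks on the mitochondrial genome were called in CTCF libraries, 1, 1, 1 and 4 of them, and in no STAG library.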
